A study of Drosophila melanogaster with 12 samples.

How the data were processed

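Gene expression was measured on 12 Affymetrix-type arrays of 18952 probe sets, each hybridised with biotin-labelled cDNA from Drosophila melanogaster ovaries. The ovaries came from virgin females 4 to 6 h after eclosion, reared at 25 °C and 70% humidity on yeast-supplemented medium. Per the labels' protocols, RNA was isolated from about 100 pairs of ovaries per biological replicate, 50 ng of total RNA was amplified to cDNA with a NuGEN kit, and 3.75 µg of cDNA was cut to fragments averaging 85 bases before labelling. There were 4 genotypes with 3 biological replicates each. The labels call the replicates biological, so the spread between arrays includes separate pools of animals.

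The deposited values are on the log2 scale and ran from 1.60 to 15.64. Per the submitters' processing notes they were made with Partek 6.5 and GCRMA, a method that subtracts a background predicted from probe sequence, normalises arrays to a common distribution and summarises the probes of each set. The order and settings of these steps are not given in the sources used here. GCRMA pulls unexpressed probe sets to a narrow range of low values. A log2 value of 5, fixed in advance, was used as the floor of measurement, and 61.9% of all values lay below it. Of the 183 control probe sets, the 143 picked by a mean under log2 4 reached at most 3.78 on any array. Picking them by low signal largely fixed this, so it does not test the floor. For a gene that stayed under this floor on every array of the dimmer side, the log2 change depends on how GCRMA sets background, so its fold is given as "at least N-fold", computed after raising values under 5 to 5. Arrays have no sequencing depth, and their number, 3 per genotype, limits the precision. Between 37.4% and 38.6% of probe sets lay over the floor on each array.

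Probe sets were named through the platform's gene table, which lists 14049 of them. Of the 18952 probe sets, 13647 named exactly 1 gene, 402 named several, 4720 had no entry and 183 were controls. Symbols were updated through gene identifiers in a RefSeq gene table (Release 6 plus ISO1 MT assembly) for 13544 of the 13647 probe sets, and 103 kept the symbol of the platform table. The sources name no genome build for the arrays, so no coordinates are given and the RefSeq table served only for names and for the order of genes. Probe sets with several genes or no entry were left out of the gene tests. Each of the 11982 genes was represented by its probe set with the highest mean over the 12 arrays. Several probe sets existed for 1094 genes. Genes over log2 5 on at least 3 of the 12 arrays were tested, which left 6163 genes. All 12 value columns were used.

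Differences were tested with limma 3.58.1 in R 4.3.3. A model with 4 genotype means was fitted to all 12 arrays, so that all comparisons share an estimate of the spread, with moderated variances that follow mean signal and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05 and a change of at least 2-fold. The comparisons were the mean of the 2 mutants minus the mean of the 2 wild types, each mutant minus each wild type, 1 wild type minus the other and 1 mutant minus the other. Consensus genes were those called in the same direction in all 4 comparisons of a mutant with a wild type. As background, the same count was made for the other 2 ways of setting 2 genotypes against 2. The level of su(Hw) was tested with an exact two-sided permutation test. Gene lists, 27 in all with 790 entries, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which does not compare a list with other genes. Of the list entries, 612 were on the array and 349 passed the filter, and 25 lists had enough members for camera. The ELAV family and chorion lists had too few.

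The text names su(Hw) and the other genes of the alleles in the labels; the 12 consensus genes with the largest rise and the 12 with the largest fall; Rbp9, elav and fne whatever their values; up to 4 called members of each list with the largest changes; and the 5 largest rises and 5 largest falls between the wild types and between the mutants. The design, gene lists, naming rule and most alternatives were chosen before the data were examined. Alternatives were other filters, a floor, median centring, cyclic loess, other rules for several probe sets, other variance models, other thresholds, a replicate block, fits of only the arrays compared and leaving out each array. Those that concern digestive enzyme genes were added after the values were seen.

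The functions were first tested on simulated data with the means and residual spreads of the 6163 genes. For mutant minus wild type, 98.5% of genes changed 4-fold were called, as were 50.7% of those changed by exactly the 2-fold minimum and 1.49% of those changed 1.5-fold, with 0 calls among unchanged genes. In the single comparisons there were at most 3 calls among unchanged genes, in Pb/2 minus BL15598. The consensus rule recovered 97.0% of the genes changed 4-fold and 10.4% of those changed 2-fold, so it misses small changes. In 20 simulated sets with no change, at most 1 gene was called in mutant minus wild type and at most 0 were consensus genes, although the 4 comparisons share arrays. Apart from the changes set, all simulated genotypes had the same mean and independent noise. The simulations thus hold no strain differences, while 314 genes were called between the real wild types. Their few false calls do not bound the calls that strain differences could give.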

Results

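Ovaries of 2 wild types and 2 su(Hw) mutants were profiled in triplicate, 12 arrays in all. Su(Hw) is a zinc-finger DNA-binding protein known from the gypsy insulator, and its loss makes females sterile. Per the labels, ovaries of this age hold egg chambers of stages 1 to 8, and mutant egg chambers undergo apoptosis at stage 9, so the comparison addresses expression before that death. The wild types were Canton S and BL15598, a y w stock with a P element in the gene CG6499, now named Amt. The mutants were su(Hw)Pb/2 and su(Hw)A2663/v, both with an X chromosome marked with y, w, ct and f alleles that Canton S does not carry. A2663/v carries the same P element as BL15598. The source label of A2663/v gives its second allele as v, while its genotype label gives su(Hw)2, the second allele of Pb/2; this disagreement was not settled here. Arrays of the same genotype correlated at 0.963 to 0.995 across tested genes, and arrays of different genotypes at 0.910 to 0.979.

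The su(Hw) transcript was nearly lost from both mutants. Its log2 signal was 9.21 ± 0.09 (SD, n = 3) in Canton S and 8.89 ± 0.13 (SD, n = 3) in BL15598, against 2.56 ± 0.07 (SD, n = 3) in A2663/v and 2.94 ± 0.42 (SD, n = 3) in Pb/2. The mutants lay at background, at least 16.5-fold below the wild types (exact two-sided permutation test, p = 0.00216, the smallest that 924 splits of 6 against 6 allow; higher in every wild-type array than in any mutant array). The permutation exchanges single arrays, although the arrays group by genotype, so its p-value is likely too low. Where the su(Hw) probe set lies relative to the lesions of the alleles was not analysed here. Of the other genes named by the alleles, f (forked, an actin-bundling protein of bristles) rose by a log2 of 3.90 ± 0.27 (SE; limma adjusted p = 1.2e-07; 3.31 with values raised to the floor), from 4.51 ± 0.08 in Canton S and 4.60 ± 1.14 in BL15598 to 8.18 ± 0.09 in A2663/v and 8.72 ± 0.27 in Pb/2 (SD, n = 3). Both mutants carry an f allele on their marked X, so the rise of f cannot be told apart from an effect of that allele. The log2 change of ct (cut) was -0.40 ± 0.16 (SE, adjusted p = 0.0559), which did not pass. The genes y and Amt were under the floor in all genotypes, and w and Polr2I had no probe set naming them alone.

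**Figure D1:**
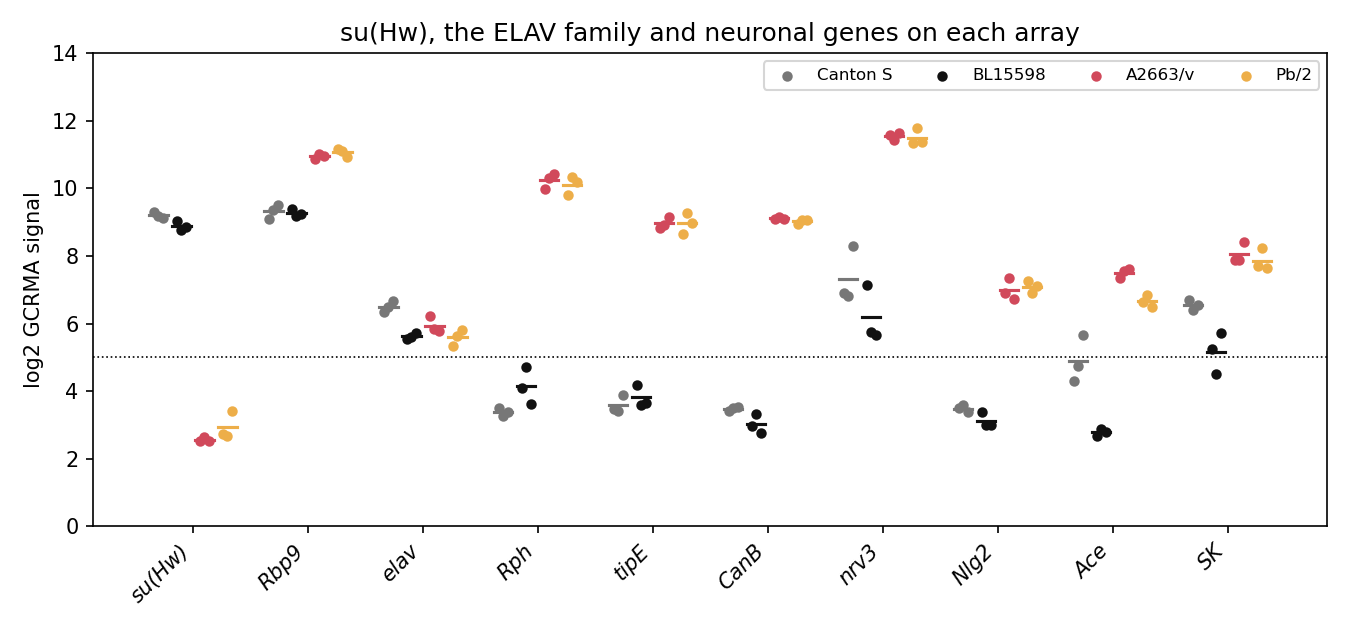
Log2 GCRMA signal (y axis) of 10 genes on each of the 12 arrays; points are arrays, short bars are means of 3, and the dotted line is the floor of log2 5. The su(Hw) values of the 6 mutant arrays lie at or under 3.42 and those of the 6 wild-type arrays at or over 8.78, while Rph, tipE, CanB and Nlg2 lie under the floor in the wild types and over it in the mutants.

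Between the average mutant and the average wild type, 245 genes were higher and 114 lower in the mutants, 359 of 6163 tested. The list of genes changed in all 4 mutant and wild-type pairs was shorter, with 79 risen and 51 fallen, and in 73 and 50 of these the 6 mutant arrays did not overlap the 6 wild-type arrays, although these genes had been selected by that difference. Against these 130 consensus genes, the other pairings of the 4 genotypes gave 12 (Canton S and Pb/2 against BL15598 and A2663/v) and 8 (Canton S and A2663/v against BL15598 and Pb/2). Over all genes tested, the 6 mutant arrays lay above the 6 wild-type arrays in 330 and below them in 512, a share of 0.137. The same 2 other pairings separated shares of 0.0247 and 0.0261, and 12 exchangeable arrays would give 0.00216, too low a value for arrays that group by genotype. Of the 359 genes, 99 also differed between the wild types, where independent lists would share 18.3, and 59 between the mutants, against 7.51. Of the 79 risen consensus genes, 43 lay under the floor on all 6 wild-type arrays, and of the 51 fallen ones 21 lay under it on all 6 mutant arrays.

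**Figure D2:**
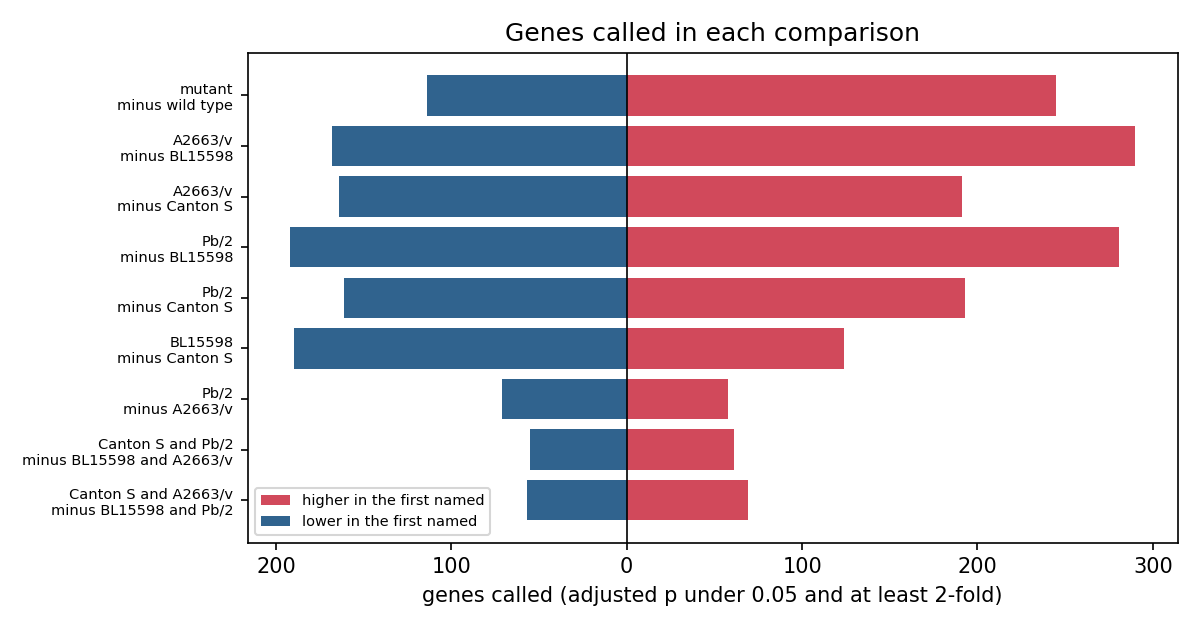
Number of genes called in each comparison (x axis), to the right those higher and to the left those lower in the genotypes named before "minus"; the lowest pair of bars are the other ways of setting 2 genotypes against 2. Mutant minus wild type gave 245 and 114 genes, and these other pairings gave 116 and 126 genes in all.

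The genes below were ranked by log2 change, and where 1 side lay under the floor that rank depends on background. Among the 12 rises ranked first, Rph, rabphilin of synaptic vesicles, was at least 36.0-fold higher in the mutants, at a log2 of 10.23 ± 0.23 in A2663/v and 10.11 ± 0.27 in Pb/2 (SD, n = 3; adjusted p = 2.79e-12). CanB, a calcineurin regulatory subunit, was at least 16.8-fold higher (adjusted p = 3.25e-13), and tipE, an auxiliary subunit of the para sodium channel, at least 15.6-fold (adjusted p = 6.72e-12). The Na,K-ATPase subunit gene nrv3 rose by a log2 of 4.76 ± 0.27 (SE) from a level over the floor in both wild types, and Hesr, a Hairy/E(spl)-related factor, by 5.12 ± 0.25 (4.05 with values raised to the floor, since 5 of 6 wild-type arrays lay under it). The other 7 were CG9813, CG1695, CG13928, CG32017, CG42857, CG2993 and CG17778, at least 5.41-fold to 15.6-fold higher. After su(Hw), the falls ranked first were CG33099 (at least 5.30-fold lower), CG42565 (log2 change -3.90 ± 0.12, SE), the cytochrome P450 gene Cyp6a20 (at least 3.40-fold lower), CG3457 (at least 5.02-fold), CG17977 (at least 1.67-fold) and GstZ1, a glutathione transferase, which lay at 6.16 ± 0.30 in A2663/v and 6.17 ± 0.38 in Pb/2 against 8.77 ± 0.22 in Canton S and 9.56 ± 0.14 in BL15598 (SD, n = 3). Next came wbl (windbeutel, a chaperone of dorsoventral patterning, at least 2.07-fold lower), CG7582 (at least 1.31-fold), CG14072, veil and CG10062 (at least 2.41-fold lower). Of the 6 mutant arrays, 5 lay under the floor for CG14072 and for veil, and with values raised to the floor their log2 changes were -0.995, under 2-fold, and -1.70.

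Of the 3 ELAV family RNA-binding protein genes on the array, 2 were tested and 1 rose. Rbp9, the member known from the ovary as well as from neurons, rose from 9.32 ± 0.21 in Canton S and 9.27 ± 0.10 in BL15598 to 10.95 ± 0.07 in A2663/v and 11.06 ± 0.13 in Pb/2 (SD, n = 3), a log2 change of 1.71 ± 0.07 (SE, adjusted p = 8.36e-10). The log2 change of elav was -0.29 ± 0.13 (adjusted p = 0.0718), which did not pass, and fne lay at 2.31 to 2.34 in all genotypes, under the floor. A second Rbp9 probe set lay at background on all arrays, and averaging both put the change at 0.85, under the 2-fold minimum.

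Neuronal ion channel genes rose as a list. Of 31 on the array only 7 passed the filter, and 4 of these rose and 0 fell, over all genes tested and adjusted over the list alone (camera adjusted p = 0.00116; adjusted p = 0.205 with an estimated correlation). The list also missed the threshold when genes were not filtered (adjusted p = 0.0506), and over 26 alternatives tested with camera its adjusted p ranged from 7.51e-05 to 0.205. Besides tipE, SK (a calcium-activated potassium channel) rose by a log2 of 2.10 ± 0.19 (SE), sei (an ERG-type potassium channel) by 1.52 ± 0.11, and NaCP60E, a voltage-gated cation channel, by 2.69 ± 0.11 (1.86 with values raised to the floor). NaCP60E differed more between the wild types, 3.33 ± 0.05 in Canton S against 7.10 ± 0.13 in BL15598 (SD, n = 3), than on average between mutants and wild types, and neither it nor sei was a consensus gene. Of 10 synaptic vesicle and active zone genes, 2 rose (Rph, and Nlg2, a neuroligin, at least 4.12-fold) and 0 fell, the median log2 change being -0.03 and the mean 0.92 (camera, upward, adjusted p = 0.258). Of 6 transmitter genes 2 rose: Ace, acetylcholinesterase, by a log2 of 1.97 with values raised to the floor, under which 5 of 6 wild-type arrays lay, and the serotonin receptor gene 5-HT1A, at least 1.36-fold (camera adjusted p = 0.232). Of 5 neuropeptide genes 2 rose: AstC at least 3.81-fold and ETH by 1.13 ± 0.15 (camera adjusted p = 0.314). Of 17 axon guidance and adhesion genes, dpr8 (at least 1.17-fold) and CadN (1.05 ± 0.21, or 0.82 with values raised to the floor) rose and NetB, a netrin, changed by -2.29 ± 0.11 (-1.91 with values raised to the floor; camera adjusted p = 0.227). Against Canton S, CadN did not pass in A2663/v (0.61, adjusted p = 0.145) or Pb/2 (0.45, adjusted p = 0.262), so its call rests on BL15598. Counts adjusted over the list alone were the same for these 4 lists. AstC was under the floor, at 4.71 and 3.61, in the 2 mutant arrays that lacked digestive enzyme signal, described further on, and at 2.58 to 2.82 in the wild types.

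Yolk and vitelline membrane genes were lower in the mutants. Of 12 tested, 7 fell and 0 rose, also adjusted over the list alone, with a median log2 change of -1.33 (camera adjusted p = 0.00116; adjusted p = 0.53 with an estimated correlation). Besides wbl, the eggshell genes Vm34Ca (-2.79 ± 0.58, SE), Vm26Aa (-2.12 ± 0.67) and psd (-1.79 ± 0.25) ranked first by log2 change, at -2.54, -1.06 and -1.21 with values raised to the floor. Vm34Ca lay at 5.15 ± 1.73 in A2663/v and 9.95 ± 1.84 in Pb/2, against 9.27 ± 0.43 in Canton S and 11.40 ± 0.31 in BL15598 (SD, n = 3), so its log2 change in Pb/2 minus Canton S was 0.67 (adjusted p = 0.573). These 3 genes were lower in A2663/v than in Pb/2 (adjusted p = 0.0022 for Vm34Ca, 0.0343 for Vm26Aa and 0.00055 for psd). Of these 12 genes and the chorion gene below, all 13 had a lower mean in each mutant than in BL15598, but 6 had a higher mean in Pb/2 than in Canton S. Only wbl was a consensus gene. The 1 chorion gene tested, chosen after its values were seen, was Cp7Fc, at a log2 change of -0.20.

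Germline lists moved little. Of 30 germline and oocyte genes 2 fell, exu (exuperantia, needed for bicoid mRNA localisation) by -1.79 ± 0.10 on the log2 scale and Pxt, a cyclooxygenase-like peroxidase, by -1.24 ± 0.08 (camera adjusted p = 0.286). Of 26 piRNA pathway genes 0 passed the 2-fold minimum, though 14 were higher at an adjusted p under 0.05 and 2 lower, with a median log2 change of 0.22 (camera adjusted p = 0.00242; adjusted p = 0.53 with an estimated correlation). Cell cycle and replication genes (0 of 23 called, median 0.17, camera adjusted p = 0.0402; adjusted p = 0.569 with an estimated correlation) and ribosomal protein genes (0 of 14 called, median 0.07, camera adjusted p = 0.00911; adjusted p = 0.53 with an estimated correlation) shifted up by little. The ribosomal list lost its call in 6 of 26 alternatives tested with camera (adjusted p from 0.000303 to 0.53), among them digestive enzyme signal as a covariate (adjusted p = 0.0604), leaving out the 4 arrays with that signal (adjusted p = 0.173), and averaging or separating probe sets (adjusted p = 0.054 and 0.0523). In the DNA damage list mus101 rose by 1.07 ± 0.09 (1 of 18; camera adjusted p = 0.102, or 0.00331 when genes were not filtered), and in the apoptosis list Buffy, a Bcl-2 relative, changed by -1.06 ± 0.11 (1 of 17; camera adjusted p = 0.722). No gene was called among 16 autophagy genes (median -0.04; camera, upward, adjusted p = 0.866; fry downward) or 16 meiosis genes (camera adjusted p = 0.258). Of 20 insulator genes su(Hw) alone fell, with a median of 0.16 and a mean of -0.17 (camera, upward, adjusted p = 0.155, or 0.0305 when genes were not filtered; fry downward). In the follicle cell list mirr rose by 1.22 ± 0.11 (1 of 17; camera adjusted p = 0.155), with a low value in BL15598, 4.41 ± 0.11, beside 8.40 ± 0.06 in Canton S (SD, n = 3). Neither mutant lay above Canton S for mirr, with means of 7.13 in A2663/v and 8.11 in Pb/2, so this change rests on BL15598. ImpL2 changed by -1.81 ± 0.19 in the ecdysone list (1 of 13; camera adjusted p = 0.72) but by -0.20 in Pb/2 minus Canton S (adjusted p = 0.598), BL15598 lying 2.29 above Canton S, and the allele genes as a list had camera adjusted p = 0.513. In these lists the calls adjusted over the list alone were the same.

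Heat shock genes were higher in the mutants, with stv, a Hsp70 co-chaperone, at a log2 change of 1.81 ± 0.21 (SE) and Hsp68 at 1.68 ± 0.21, 2 of 10 tested (camera adjusted p = 0.00448; adjusted p = 0.53 with an estimated correlation). Of 8 immune effector genes Mtk, the peptide metchnikowin, was at least 1.63-fold higher (camera adjusted p = 0.0463; adjusted p = 0.447 with an estimated correlation). This list lost its call in 15 of 26 alternatives tested with camera (adjusted p from 0.00116 to 0.447), among them digestive enzyme signal as a covariate (adjusted p = 0.0634) and leaving out the 4 arrays with that signal (adjusted p = 0.0654). Among haemocyte genes Pxn rose by 2.69 ± 0.19 (2.34 with values raised to the floor) and NimC1 was at least 1.93-fold lower, 2 of 13 (camera adjusted p = 0.258). Against BL15598 the log2 change of NimC1 was -0.48 in A2663/v (adjusted p = 0.258) and under 2-fold in Pb/2, so its call rests on Canton S. Of 6 testis genes vis was at least 1.21-fold lower (camera adjusted p = 0.155). Muscle and sheath (0 of 18, camera adjusted p = 0.286) and fat body lists (0 of 12, camera adjusted p = 0.305) held no called gene. Of the list members named here, sei, NaCP60E, ETH, CadN, Pxt, mirr, Buffy, ImpL2, NimC1, Vm34Ca, Vm26Aa and psd were not consensus genes.

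Digestive enzyme genes, markers of gut, were over the floor in some dissections. Of 8 gut genes tested, 4 were called higher in the mutants, thetaTry, Jon65Aiii, Jon44E and Mal-A2, and 5 when adjusted over the list alone (camera adjusted p = 0.0402; adjusted p = 0.569 with an estimated correlation). The list lost its call in 16 of 26 alternatives tested with camera (adjusted p from 0.00105 to 0.694), and Jon65Aiii lost its own in 19 of 25 and thetaTry in 14 of 25. The 7 digestive enzyme genes of this list were averaged, its Npc2 genes being left out after their values were seen. Their mean log2 signal was 6.60 and 7.94 in Pb/2 replicates 1 and 2 and 6.84 and 7.86 in A2663/v replicates 1 and 3, against 2.44 in Pb/2 replicate 3 and 2.28 in A2663/v replicate 2. In the wild types it was highest in BL15598 replicate 2, at 4.79. Single genes lay over the floor there too, alphaTry at 7.34, Mal-A1 at 7.14 and Jon65Aiii at 5.54. Mal-A1 was at 6.02 in BL15598 replicate 1. In Canton S replicate 3 alphaTry was at 5.54, Mal-A1 at 5.57 and thetaTry at 5.02. On the other wild-type arrays all 7 genes lay under the floor. The 4 arrays with digestive enzyme signal named elsewhere are Pb/2 replicates 1 and 2 and A2663/v replicates 1 and 3, and leaving them out keeps all wild-type arrays. Without these 4 mutant arrays, an alternative chosen after seeing the data that leaves 1 array per mutant and assumes it varies like the wild types, 101 consensus genes were called, 91 of them among the 130. Of 3 RNA quality measures, 2 differed: the 3′ minus 5′ log2 signal of the GAPDH control was 2.42 ± 0.10 in mutants and 2.01 ± 0.24 in wild types (SD, n = 6; exact permutation p = 0.00866, adjusted p = 0.018 over 5 measures), and that of eIF-4a 3.01 ± 0.22 against 2.31 ± 0.38 (exact permutation p = 0.0108, adjusted p = 0.018), while that of actin was 1.20 ± 0.14 against 1.04 ± 0.22 (exact permutation p = 0.147). The share of probe sets over the floor was 38.3% in mutants and 37.8% in wild types (exact permutation p = 0.00866, adjusted p = 0.018). These permutation tests exchange single arrays, although the arrays group by genotype, so their p-values are likely too low. The effect of the RNA quality differences on the called genes and lists, the heat shock genes among them, was not tested.

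**Figure D3:**
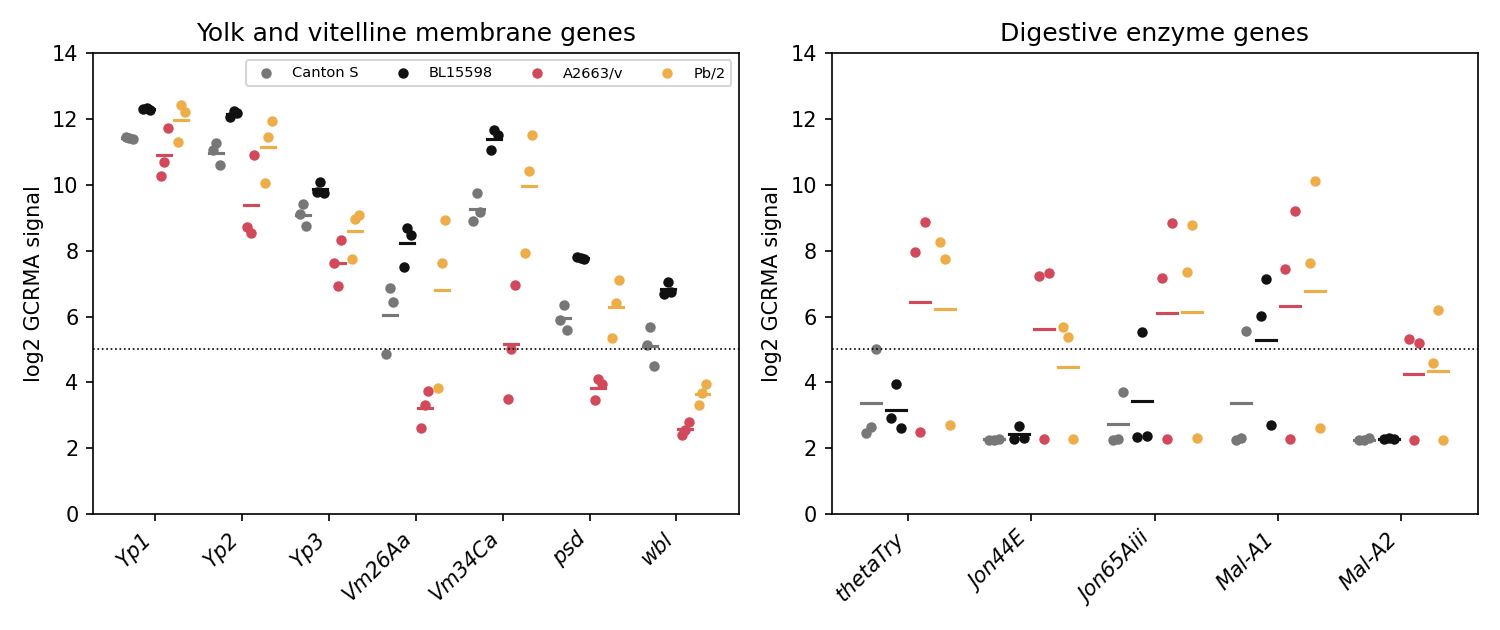
Log2 GCRMA signal (y axes) of yolk and vitelline membrane genes (left) and digestive enzyme genes (right) on each array; points are arrays, short bars are means of 3, the dotted line is the floor of log2 5. Vm34Ca has a mean of 5.15 in A2663/v and 9.95 in Pb/2, and in each mutant 1 array lies near background for the digestive enzyme genes.

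Genotype by genotype, A2663/v differed from BL15598, which shares its P element, in 290 genes higher and 168 lower, and from Canton S in 191 and 164. Pb/2 differed from BL15598 in 281 and 192 genes and from Canton S in 193 and 161. Rbp9, Rph and su(Hw) were among the genes called in each of these 4 comparisons. To compare the mutants without a shared control array, A2663/v minus BL15598 was set against Pb/2 minus Canton S. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.55 (Spearman's rho 0.42). They shared 100 risen genes, where independent lists would share 9.08, and 56 fallen genes, against 4.39, while 21 were called in opposite directions, against 12.8. The second such pairing, A2663/v minus Canton S with Pb/2 minus BL15598, gave r = 0.53, 95 risen genes against 8.71 and 68 fallen against 5.11. If the second allele of A2663/v is su(Hw)2, as its genotype label has it, the mutants share that chromosome as well as the marked X, and this agreement was not separated from it. The wild-type difference and the mutant difference, which involve no loss of su(Hw), correlated at r = -0.03.

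**Figure D4:**
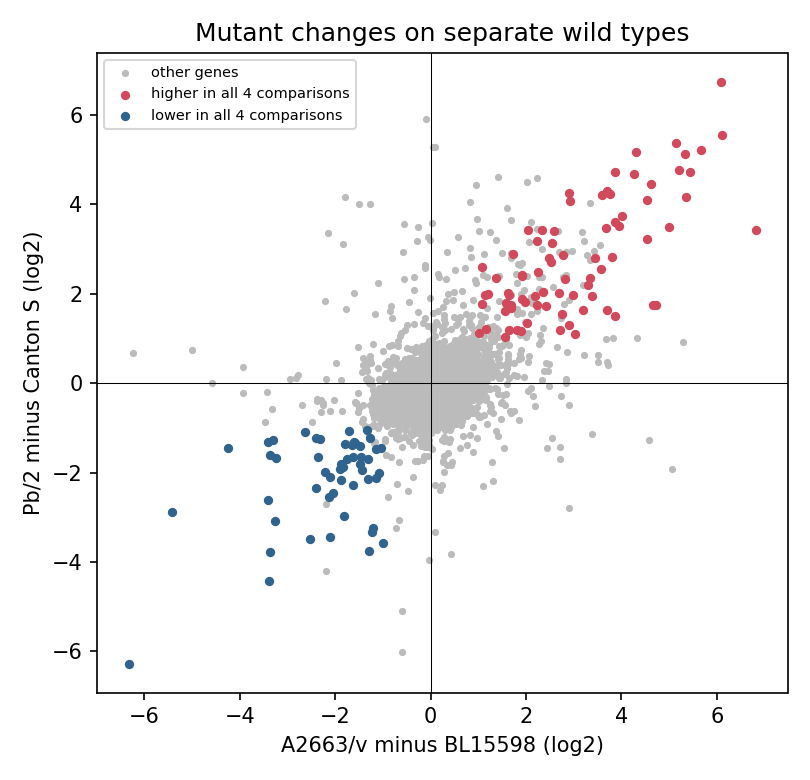
Log2 change of each tested gene in A2663/v minus BL15598 (x axis) and in Pb/2 minus Canton S (y axis), with the 79 risen and 51 fallen consensus genes coloured. The changes correlated at r = 0.55 across 6163 genes.

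The wild types differed from each other in 314 genes, 124 higher and 190 lower in BL15598. Ranked by log2 change, with Canton S under the floor for all 5, the first rises were CG31219 (at least 11.7-fold), Arpc1 (an Arp2/3 subunit, at least 11.6-fold), CG4570 (at least 6.89-fold), Elovl7 (a fatty acid elongase, at least 12.6-fold) and CG8539 (at least 8.59-fold). Oat, ornithine aminotransferase, was at least 58.3-fold lower in BL15598, at 2.72 ± 0.35 beside 10.87 ± 0.17 in Canton S (SD, n = 3; adjusted p = 4.65e-13). CG18545 was at least 7.50-fold, tut at least 12.2-fold, CG17470 at least 3.45-fold and mirr at least 10.6-fold lower. The mutants lay nearer to BL15598 than to Canton S for 141 (A2663/v) and 137 (Pb/2) of the 314 genes.

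The mutants differed from each other in 129 genes, 58 higher and 71 lower in Pb/2. Vm34Ca (log2 change 4.79 ± 0.82, SE) and Vm26Aa (at least 4.57-fold) were higher in Pb/2, as were CG18545 (at least 3.15-fold), Pis, a phosphatidylinositol synthase (3.85 ± 0.31), and Dh44-R2, a diuretic hormone receptor (at least 1.62-fold). A second Pis probe set that passed the filter, of mean 5.39, changed by only -0.19 in mutant minus wild type, against -2.08 for the one used. The Pis call was kept over 25 alternatives, at a log2 change of 1.29 to 4.71. CG9917 (at least 33.9-fold), Zip102B, a zinc transporter (at least 8.69-fold), CG32625 (-4.14 ± 0.09), the immune gene PGRP-SB1 (at least 4.38-fold) and Send1, a spermathecal endopeptidase (at least 5.90-fold), were lower in Pb/2. Send1 lay over the floor in A2663/v at 7.56 ± 2.08 and varied in Canton S, 4.40 ± 3.36 (SD, n = 3). The calls of Send1 and Vm26Aa each depended on single arrays: without A2663/v replicate 1 the adjusted p was 0.116 for Send1 and 0.118 for Vm26Aa. Without the 4 arrays with digestive enzyme signal, 72 genes were called, 52 of them among the 129, and PGRP-SB1 lost its call (-2.51, adjusted p = 0.431).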

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

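The tests of gut tissue were chosen after the values were seen; the other tests in this part were chosen before. Of the genes named for mutant minus wild type and called there, 9 were also called in Pb/2 minus A2663/v with limma, at an adjusted p under 0.05 and at least 2-fold. In 3 of the 9, wbl, CG10062 and CG14072, the means of both mutants lay under the floor, so no difference between the mutants was measured. The log2 differences of the other 6 were -1.90 for Hesr (adjusted p = 0.00358), -1.37 for CG42565 (adjusted p = 0.000175), -2.19 for NetB (adjusted p = 1.04e-06), 4.79 for Vm34Ca (adjusted p = 0.0022), 3.58 for Vm26Aa (adjusted p = 0.0343) and 2.45 for psd (adjusted p = 0.00055). NetB in Pb/2 and Vm26Aa and psd in A2663/v lay under the floor on all 3 arrays, so the sizes of these 3 differences depend on background. Outside the gene tests, 24 probe sets without a single gene name were called in all 4 mutant and wild-type comparisons, 17 higher and 7 lower, of 933 that passed the filter.

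Of 100 assignments of the 12 arrays to 4 groups, the real one included, only 1 gave as many consensus genes, the real 130. The highest other was 0. For the 359 genes of mutant minus wild type it was also 1, with a highest other of 138. Such assignments mix genotypes within groups, so they exclude chance only as a grouping of single arrays. With genotypes kept whole there are only 3 pairings, too few to exclude chance. The other 2 gave 12 and 8 consensus genes and 116 and 126 called genes. Only 1.56% of the 128 mapped consensus genes other than su(Hw) lay among the 300 genes next to su(Hw), where 1.76% of tested genes lie. This argues against changes in the genes of a chromosome segment carried along with the alleles as the cause. Effects of such a segment on genes elsewhere were not tested. The share on the X chromosome was 31.2%, with an exact 95% interval from 23.4 to 40.0, so under 50% of the genes lie there. This bounds only an effect of the marked X of the mutants on its own genes, and its effects on genes elsewhere were not tested. The share was above the 17.0% of tested genes there (Fisher's exact p = 6.76e-05). An effect of this X on the list stays open. For gut tissue, 10.1% of the risen consensus genes, 8 of 79, were lower by a log2 of 1 or more in the 2 mutant arrays without digestive enzyme signal. This was just over the bound of 10% set to exclude it, so for these 8 genes, AstC and Mtk among them, gut tissue remains a possible source. Of the 79, 92.4% lay above all wild-type arrays in both of those arrays, so most rises were also present where digestive enzyme signal was near background. But the genes had been selected by that difference on the same arrays, and AstC and Mtk passed as well. This measure therefore does not exclude gut tissue. Loss of Su(Hw), shared by both mutants, remains a hypothesis for the consensus genes other than su(Hw), found and tested on the same arrays. It was not separated from the marked X, for f not from its allele in the mutants, and for the 8 genes above not from gut tissue.

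For the neuronal genes, nervous tissue in the mutant dissections was tested with 9 abundant pan-neuronal genes on the array, fixed in advance. Their median log2 change was -0.00305 and 1 of 9, elav, lay over the floor in a mutant; nSyb, Syn, brp and para stayed at background. This argues against neurons as the source of Rph, tipE and the others, as far as these probe sets detect neurons. All arrays were of ovaries, so that detection could not be checked here. The 3′ minus 5′ signal of control genes differed between mutants and wild types, and its effect on these genes was not tested.

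For the yolk and vitelline membrane genes, 92.3% of 13 yolk, eggshell and chorion genes moved in the same direction, 12 lower and 1 higher on average, as a younger mean stage of the mutant egg chambers predicts. This did not hold in every comparison: in Pb/2 minus Canton S 7 were lower and 6 higher, and the median change against the wild types was -1.54 in A2663/v and -0.42 in Pb/2. Genes expressed together are not independent, so no p-value is given. A different stage mix may underlie this pattern, and a direct effect of the mutations was not separated from it.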

How the results depend on the processing

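The alternatives built on digestive enzyme signal were chosen after seeing the data. The loss of su(Hw) kept its direction and call throughout, -6.42 to -6.23 without single arrays and -4.05 with values raised to the floor. Left-out arrays gave 331 to 388 genes for mutant minus wild type, 115 to 150 consensus genes, 411 to 523 for A2663/v minus BL15598, 329 to 408 for A2663/v minus Canton S, 449 to 500 for Pb/2 minus BL15598, 335 to 417 for Pb/2 minus Canton S, 283 to 345 for BL15598 minus Canton S, 99 to 132 for Pb/2 minus A2663/v, 6 to 8 lists, and r of 0.50 to 0.58 and 0.48 to 0.57 for the 2 pairings of mutants. With the filter at log2 7, 210 were called in mutant minus wild type, 298 and 224 in A2663/v minus BL15598 and minus Canton S, 296 and 219 in Pb/2 minus BL15598 and minus Canton S, 207 between wild types, 70 between mutants and 83 in consensus. With no minimum change these counts were 2892, 2521, 1658, 2635, 1759, 1564, 495 and 582, and with 1.5-fold 787, 1151, 735, 1134, 780, 688, 294 and 250. Without a minimum the falls outnumbered the rises in mutant minus wild type, 1641 to 1251.

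The list count depended most on the method: against 8 it was 4 without the variance trend, 5 without moderation, 5 with digestive enzyme signal as a covariate, 5 without the 4 arrays that had it, 0 with an estimated correlation and 17 with fry; apart from the estimated correlation, the cause was not tested. The yolk list failed only with the estimated correlation, and the ion channel list with it (adjusted p = 0.205) and with no filter (adjusted p = 0.0506). Of 100 array assignments, 15 gave as many lists, the highest other giving 11, so chance is not excluded for their number. Without the 4 arrays, picked for high values of these genes, the gut list (camera's unadjusted value 0.600, adjusted p = 0.653), thetaTry (-0.68), Jon65Aiii (-0.79), Jon44E (-0.058) and Mal-A2 (-0.019) turned negative, which that choice fixed, so it shows nothing about the mutants; r fell to 0.44 and 0.40, and 72 genes were called between the mutants.

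Of 78 results for 74 named genes, 57 always kept direction and call. Only 5 uncalled lists of 25 kept call status. With values raised to the floor CadN, mirr, NimC1, Mtk and 9 others fell under 2-fold, since that removes change below the floor, and Vm26Aa and Send1 lost their adjusted p. Among those 9, dpr8, vis and Mal-A2 did too (limma adjusted p = 0.0831, 0.0521 and 0.204). Averaging probe sets put Rbp9, exu and mirr under 2-fold. Left-out arrays undid calls (adjusted p in brackets; the cause was not tested). Send1 lost its call without Pb/2 replicates 1, 2 and 3 and A2663/v 1 and 2 (0.0597 to 0.116). Vm26Aa lost it between the mutants without BL15598 3, Pb/2 2 and 3 and A2663/v 1, 2 and 3 (0.0502 to 0.123), and between mutants and wild types without Canton S 2 (0.0502). The latter call was lost in 7 of 25 alternatives (0.00188 to 0.166), among them no filter (0.0673), robust variances (0.0702), no moderation (0.0789), the enzyme covariate (0.126) and without the 4 arrays (-1.01, 0.166). CadN fell under 2-fold without BL15598 2, Pb/2 2 and 3 and A2663/v 1 (log2 0.90 to 0.99). thetaTry missed without Canton S 1 and 2, BL15598 1 and 3, Pb/2 1 and 2 and A2663/v 1 and 3 (0.0656 to 0.0887), and Jon65Aiii without these or Canton S 3 (0.0503 to 0.120). The gut list missed without Canton S 1 and 2, BL15598 3, Pb/2 1 and 2 and A2663/v 1 and 3 (0.0522 to 0.0945), the immune list without Canton S 1 and 3, BL15598 3, Pb/2 1 and A2663/v 3 (0.0522 to 0.0796), and the cell cycle list without BL15598 2 (0.057) or A2663/v 2 (0.0555). The follicle list passed without Canton S 3 (0.045), and with no filter the DNA damage (0.00331) and insulator lists (0.0305) did.

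The 6-array comparisons allow only 10 splits each, too few for a share under 0.05; the real split, 1 of 10 in each, gave 458, 355, 473, 354, 314 and 129 genes and the highest other 0, 3, 0, 0, 0 and 3. Replicate numbers did not pair the arrays throughout: deviations of same-numbered ones correlated from -0.53 to 0.37. A batch shared by some same-numbered arrays is not excluded. With the replicate block, 359 genes were called in mutant minus wild type, 129 in consensus and 8 lists, and Jon65Aiii lost its call (adjusted p = 0.064).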

Other observations

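The families and the X chromosome sets here were chosen after the values were seen; the neighbour test and its bound were fixed before it was run, but its draw within chromosomes was added after the X chromosome result was seen. Of 23 cytochrome P450 genes tested, 3 rose and 4 fell in mutant minus wild type, 0 were higher and 2 lower in BL15598 than in Canton S, and 1 was higher and 1 lower in Pb/2 than in A2663/v. Of 22 glutathione transferase genes these numbers were 1 and 2, 5 and 1, and 1 and 2. Of 4 dpr genes they were 3 and 0, 1 and 1, and 0 and 0. Among genes outside the P450 family 5.73% were called in mutant minus wild type, 5.08% between the wild types and 2.07% between the mutants. The 3 families were picked because called members had been seen, so no p-value is given.

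The X chromosome held 27.8% of the mapped risen and 36.7% of the fallen consensus genes (Fisher's exact p = 0.0152 and 0.000832, adjusted p = 0.0379 and 0.00416 over 5 sets), against 17.0% of tested genes. The share among all genes called in mutant minus wild type, 20.6%, did not pass (Fisher's exact p = 0.0688, adjusted p = 0.115). Genes called between the wild types (16.5%) and between the mutants (14.3%) did not pass either (Fisher's exact p = 0.817 and 0.473). Both mutants carry a marked X, and the su(Hw) transcript was at background in both, so the share of 31.2% may reflect either; the design cannot separate them for these genes.

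The hypothesis that neighbouring genes change together was tested by counting consensus genes adjacent in gene order among tested genes. There were 7 such pairs, against a mean of 2.65 in 10000 random sets (one-sided permutation p = 0.0161) and 3.15 when sets were drawn within chromosomes (permutation p = 0.0353), where 7 is also the upper 95% limit. In 5 of the 7 pairs both genes moved the same way, as for CanB and SK (5.82 and 2.10), and Cyp6a17 and Cyp6a23 moved apart (4.25 and -1.64). CG11638 paired both with CG3699 and with CG32814, so the pairs are not all independent. Shared regulation may be a candidate explanation, but related neighbours on an array could also share hybridisation, which was not tested. An effect of the marked X of both mutants on neighbouring genes was not separated from it either.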
